A study of Gallus gallus with 10 samples.

How the data were processed

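Single-cell RNA sequencing was done on CD45+ cells of the chicken spleen, with 1 library per bird. There were 10 libraries in 4 groups: 3 infected Cobb birds, 3 Cobb controls, 1 infected Beijing-you bird and 3 Beijing-you controls. The authors deposited, per library, a gene-by-barcode matrix of raw UMI counts made with Cell Ranger 3.1.0 against genome build GRCg6a. The matrices listed the same 24356 Ensembl genes, of which 10821 carried no symbol, and together held 56962 barcodes. The smallest barcode had 500 UMIs, so barcodes below that number were already absent. The files give no chromosome or position for a gene, so genes are identified by symbol and Ensembl identifier, and genes without a symbol were tested and counted but not named.

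Cells were kept with at least 500 UMIs, at least 200 genes, a mitochondrial share of at most 15% (13 mitochondrial genes were matched) and no doublet call. Doublet scores came from scrublet as run by scanpy 1.11.5. Its automatic threshold called only 16 barcodes (0.0281%), and after this was seen the threshold was replaced by a rank: the highest-scoring barcodes of each library were removed, at 0.8% per 1000 barcodes, which removed 2657 barcodes (4.66%). After all filters 24258 cells (42.6%) were kept. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 nearest neighbours were used for Leiden clustering (leidenalg 0.10.2) at resolution 1.0 with seed 1. The 29 clusters were named from marker lists written in advance, by the mean of each marker's level as a share of its highest level over clusters, with a minimum of 0.25 and 3 detected markers (20 CPM or more). No other class could have more markers than the named one among the 10 leading genes. The macrophage or monocyte clusters of 309 and 246 cells each held 1 marker of another class among these genes. Clusters that met no class were left unnamed (3 clusters). The marker lists were set in advance, but the thresholds of the naming rule and its rule for near ties (scores within 0.05, decided by the leading genes) were set after clusters were seen. The near-tie rule named 1 cluster of 1746 cells as NK or cytotoxic lymphocytes. The result was 9 classes. No batch integration was applied across libraries.

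For gene tests, raw UMI counts of the kept cells were summed per library, so that birds and not cells were the replicates. The sums held 2854000 to 13121000 UMIs. Genes passing filterByExpr were fitted in edgeR 4.0.16 (TMM factors from 0.775 to 1.23, robust quasi-likelihood F test) in a model with 4 groups and 6 residual degrees of freedom. The single infected Beijing-you library adds none of these and was assumed to vary like the other groups. The common biological coefficient of variation was 0.211 for all cells. The 5 comparisons were infection within Cobb, breed among controls, infection within Beijing-you, breed under infection, and the difference between the infection effects of the breeds. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Log2 fold changes are given with their SE, and group levels as mean CPM (UMI counts scaled to a common library total) with the SD between libraries. The first 2 comparisons were repeated on sums within each class with at least 30 cells in every library. These were T cells (10881 cells, 122 in the smallest library), NK or cytotoxic lymphocytes (4240 cells, 154), B cells (4171 cells, 103) and macrophages or monocytes (765 cells, 43).

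Shares of cells per class were compared with exact two-sided permutation tests over libraries, adjusted by Benjamini-Hochberg over 10 classes (unnamed cells counted as one). With 3 libraries against 3 the smallest p is 0.1, so no share could pass 0.05. Shares of the single infected Beijing-you library carry exact 95% Clopper-Pearson intervals, which cover counting error only. The 21 gene lists, covering immune, metabolic, stress and other-cell-type genes, were tested with camera in limma 3.58.1 at the preset correlation of 0.01, adjusted over the lists of a comparison, with the estimated correlation beside it. The fry test of limma was run on the same lists, as set in advance. Lists needed at least 3 measured members. The direction of the response was compared as the share of genes called in Cobb whose change in Beijing-you had the same sign. Groups, comparisons, tests, marker lists, gene lists and the rule for named genes were set before the data were examined.

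Under that rule, named genes were those with the largest absolute log2 fold change among called genes with a symbol, a mean of at least 10 CPM in the higher group and libraries that did not overlap between groups. There were up to 10 per direction for the main comparisons, 5 per direction for comparisons with the single infected Beijing-you bird and 4 per direction within a class. From each list described, up to 4 members with the smallest adjusted p were taken. Any other gene value, such as HINTW, CD3E by cluster or IGLL1 within T cells, was chosen after values were seen.

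The alternatives set in advance were RLE size factors, the DESeq2 1.42.0 Wald test, no low-count filter, no cell filter, a stricter cell filter (1000 UMIs, 500 genes, mitochondrial share of at most 5%), doublets kept, 22 haemoglobin, immunoglobulin and mitochondrial genes left out, an equal draw of 1062 cells per library, only the 6 libraries compared, a replicate block, classes from clustering each library on its own, Leiden resolutions of 0.5 and 2.0, and each replicate left out in turn. Chosen after the data were seen were a mitochondrial share of up to 30%, W-linked RNA as a covariate (HINTW above 100 CPM in a library), the near-tie cluster left unnamed, and further settings for the direction of the response. Without a cell filter and at a mitochondrial share of up to 30%, classes came from a separate clustering and naming of all barcodes. These settings thus changed the class labels as well as the filter. The pipeline was tested on simulated counts with 200 changed genes per set. For the Cobb infection comparison in all cells, edgeR recovered 45% of the genes changed by a log2 fold of 1 and 81% of those changed by 2. For infection within Beijing-you these were 14% and 60%, and for macrophages or monocytes in the Cobb infection comparison 14% and 54%. In the simulated Cobb infection set of all cells edgeR also called 12 unchanged genes, and in that of macrophages or monocytes 6. A simulated list of unchanged genes had an unadjusted camera p of 0.0123 in the control breed set and 0.0742 or more in the others. Other software was R 4.3.3, python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Dendritic, plasma, erythroid, granulocyte and thrombocyte classes were left out of the gene tests because a library held fewer than 30 of their cells. Sequence reads were not used here.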

Results

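Spleen CD45+ cells (CD45 marks leukocytes) were profiled by droplet single-cell RNA sequencing in chickens of 2 breeds, the Cobb broiler, a fast-growing commercial line, and Beijing-you, a Chinese local breed. Birds were 28 days old when given Salmonella typhimurium or buffer by mouth, and spleens were taken 3 days later. There were 3 infected Cobb birds, 3 Cobb controls, 1 infected Beijing-you bird and 3 Beijing-you controls. The infected Cobb libraries held 10260624, 10880876 and 16504114 UMIs, and the Cobb control libraries 12845860, 6455946 and 10594104. The infected Beijing-you library held 13922683 UMIs, and the Beijing-you control libraries 6627158, 7879737 and 7387452. After filtering, 3835, 3435 and 4526 cells remained in the infected Cobb libraries and 1905, 1235 and 1062 in the Cobb controls. The infected Beijing-you library kept 3897 cells, and the Beijing-you controls 1202, 1394 and 1767.

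Cell quality differed with infection. The median mitochondrial share of UMIs was 9.99% ± 0.411 (SD, n = 3) in infected Cobb libraries and 22.3% ± 2.41 (n = 3) in Cobb controls. It was 11.7% in the infected Beijing-you library and 19.4% ± 1.504 (n = 3) in Beijing-you controls. The filters kept 67.1% ± 2.44 of the barcodes of infected Cobb libraries and 23.5% ± 6.37 of those of Cobb controls. The W-linked transcript HINTW, carried by females, was near 0 in all 3 infected Cobb libraries, in Cobb control 1 and in Beijing-you control 1, and was at 942 CPM or more in the other libraries. Within Cobb, infection thus went with its absence except in control 1.

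The first comparison asked how infection changed the splenic leukocytes of Cobb birds. T cells made up 56.1% ± 4.24 (SD, n = 3) of the cells of infected Cobb birds and 18.9% ± 6.48 (n = 3) of those of Cobb controls. B cells made up 15.4% ± 1.504 and 10.3% ± 0.549. Plasma cells, which secrete antibody, fell to 0.595% ± 0.173 from 14.2% ± 6.99. Macrophages or monocytes fell to 1.59% ± 0.336 from 5.33% ± 1.75, and dendritic cells to 0.841% ± 0.150 from 4.18% ± 0.531. NK or cytotoxic lymphocytes made up 18.3% ± 0.627 and 30.3% ± 2.65 of cells, and their clusters also expressed the T cell gene CD3E (736.6, 907.3 and 1014 CPM). Erythroid cells fell to 0.0248% ± 0.0262 from 5.88% ± 3.09, and thrombocytes to 0.0368% ± 0.0320 from 0.293% ± 0.185. In each of these 8 classes the infected and control libraries did not overlap, with an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give (adjusted p 0.125). The granulocyte share did not separate the groups (exact permutation p 0.8), nor did that of unnamed cells (7.03% ± 3.26 against 10.5% ± 4.02, exact permutation p 0.5). The granulocyte class held only 8 infected and 2 control Cobb cells. An unnamed cluster led by EXFABP, S100A12, MMP9 and CSF3R held 19.4% of the unnamed cells of Cobb controls and 2.52% of those of infected birds. These were 40, 32 and 11 cells in the control and 1, 1 and 18 in the infected libraries. Without a cell filter the difference was 17.2 points instead of 37.2 for T cells and -2.91 instead of -13.6 for plasma cells. It was -1.57 instead of -5.86 for erythroid cells and -1.99 instead of -3.74 for macrophages or monocytes (exact permutation p 0.2 for the latter). That of NK or cytotoxic lymphocytes reversed, to 3.07 points higher in infected birds (18.25% against 15.19%). Its exact permutation p was 0.1, the same as that of the main difference. All barcodes were clustered and named anew in this setting, so cells could also change class, and the changes are not those of the filter alone. At a mitochondrial share of up to 30% the difference of NK or cytotoxic lymphocytes was -1.38 (exact permutation p 0.5). With the stricter cell filter T cells were at 64.5 points, plasma cells at -41.6, macrophages or monocytes at -6.89 and B cells at 0.436 instead of 5.05 (p 0.7), and the libraries overlapped in dendritic cells (p 0.4), as they did with each library clustered on its own in dendritic and in erythroid cells (p 0.4 each).

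**Figure D1:**
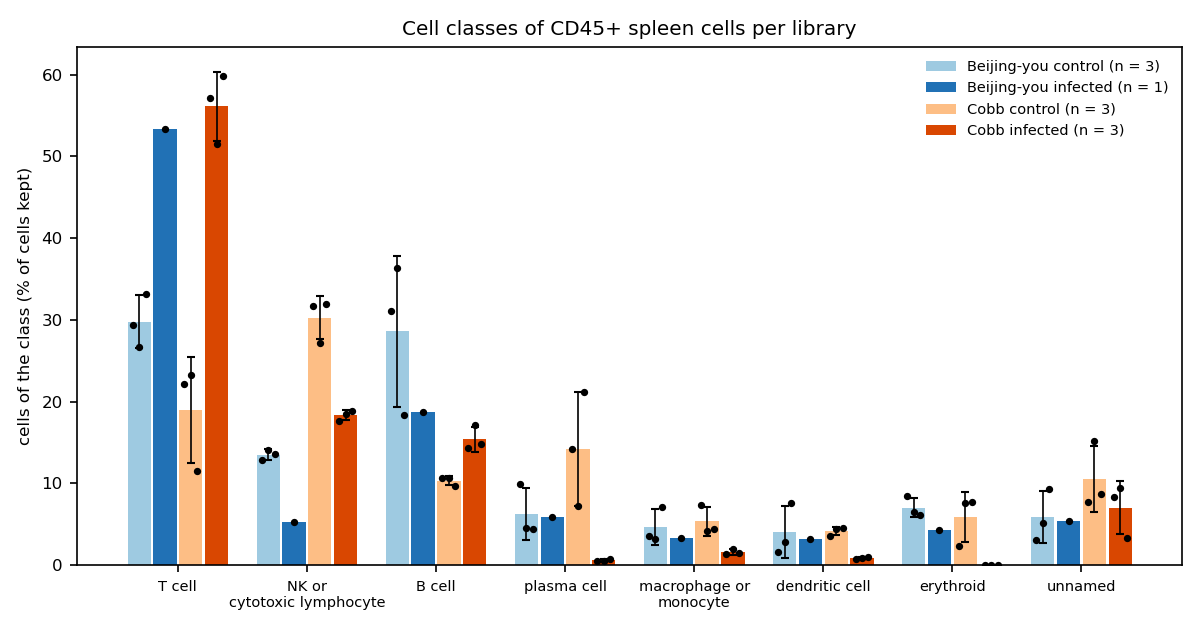
Share of kept cells (%, y axis) in each cell class (x axis) for the 4 groups; bars are group means, error bars the SD between libraries and points the libraries. T cells made up 56.1% of the cells of infected Cobb birds and 18.9% of those of Cobb controls, and plasma cells 0.595% and 14.2%.

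Across all CD45+ cells, ICOS, CCL20, CEBPD, FSTL4 and FHL3 were among the genes with more RNA in infected Cobb birds. ICOS (ENSGALG00000008656), a costimulatory receptor of T cells, was at 384.6 ± 48.5 CPM (SD, n = 3) against 80.6 ± 28.9 in controls (log2 fold change 2.26 ± 0.247 SE, edgeR adjusted p 0.000279). CCL20 (ENSGALG00000003003), the chemokine that binds CCR6, was at 67.0 ± 32.4 against 8.22 ± 7.17 CPM (2.91 ± 0.723, adjusted p 0.0216). CEBPD (ENSGALG00000040180), a transcription factor of inflammatory responses, was at 144.6 ± 42.5 against 24.2 ± 2.86 CPM (2.58 ± 0.257, adjusted p 0.000162), with its highest level in NK or cytotoxic lymphocytes. FSTL4 (ENSGALG00000031487), a follistatin-like secreted protein, had the largest increase, to 56.5 ± 31.2 from 1.90 ± 1.32 CPM (4.85 ± 0.585, adjusted p 0.000591). FHL3 (ENSGALG00000035187), a LIM-domain protein, rose to 155.4 ± 9.21 from 31.7 ± 5.12 CPM (2.30 ± 0.201, adjusted p 4.96e-05). The other largest increases were MTSS2 (3.21 ± 0.658), the selenoprotein gene SELENOW (2.84 ± 0.596), CYB561D2 (2.42 ± 0.429), the RNA helicase gene DDX4 (2.29 ± 0.489) and the potassium channel gene KCNH4 (2.25 ± 0.356). The calls of MTSS2, CCL20, SELENOW and DDX4 were lost under at least 1 alternative. ICOS, CCL20, MTSS2, CYB561D2, DDX4 and KCNH4 had their highest level in T cells, whose share rose to 56.1% from 18.9%. The larger T cell share can thus carry part of these increases. ICOS belongs to the T cell activation list, whose result within T cells is given below.

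Many of the largest decreases were of genes with their highest level in classes whose share fell. The haemoglobin genes HBAD, HBA1 and HBBA fell by 8.70 ± 1.53, 8.11 ± 1.42 and 7.95 ± 1.18 on the log2 scale, HBBA (ENSGALG00000047152) to 4.41 ± 3.33 from 1094 ± 706 CPM (n = 3 each, edgeR adjusted p 0.00370). In the infected libraries HBAD was at 2.1, 0.242 and 0.0817 CPM and HBA1 at 7.88, 0 and 1.80 CPM. The size of their falls thus rests on levels near 0. The anion exchanger gene SLC4A1 (-6.44 ± 1.54), the haematopoietic transcription factor gene TAL1 (-5.00 ± 0.483) and the intermediate filament gene SYNM (-4.72 ± 0.550) also had their highest level in erythroid cells. MMP13 (ENSGALG00000017183), a collagenase, fell to 0.720 ± 0.157 from 30.3 ± 7.85 CPM (-5.33 ± 0.321, adjusted p 8.72e-06). BLVRA (ENSGALG00000031786), which reduces biliverdin, fell to 1.42 ± 0.227 from 39.8 ± 11.7 CPM (-4.77 ± 0.444, adjusted p 0.000141). MMP13, BLVRA and CNTNAP1 (-4.67 ± 0.697) had their highest level in plasma cells, and ARHGAP22 (-4.90 ± 0.480) in dendritic cells. The call of SLC4A1 was lost under 8 of 18 alternatives and that of ARHGAP22 under the stricter cell filter.

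Of 11855 genes tested, 3319 were called, 1569 higher and 1750 lower in infected Cobb birds, 666 of them without a symbol. DESeq2 called 3314, and 1648 of the edgeR calls were at least 2-fold. The libraries of the groups did not overlap for 5237 genes (44.2%, where chance gives 10% for 3 against 3). Without infected Cobb replicate 1 the count was 2141, without replicate 2 it was 2185, and the stricter cell filter left 1623.

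**Figure D2:**
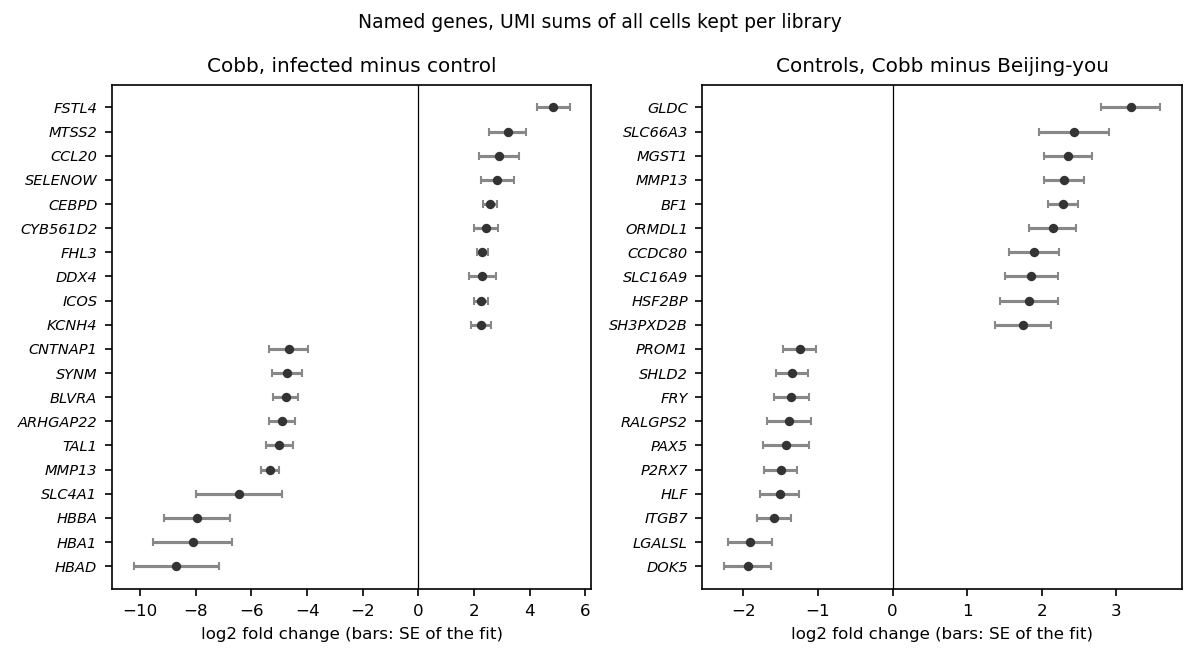
Log2 fold change (x axis, error bars SE) of the 20 named genes (y axis) of each main comparison in all CD45+ cells, with infected minus control Cobb on the left and control Cobb minus control Beijing-you on the right. In infected Cobb birds FSTL4 rose by 4.85 and HBAD fell by 8.70; among controls GLDC was at 3.19 and DOK5 at -1.94.

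Genes of T cell activation and checkpoints rose as a list in infected Cobb birds: of 20 measured, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a camera adjusted p of 2.11e-05 (adjusted p 0.186 with the estimated correlation). CD28, the costimulatory receptor, rose by 1.77 ± 0.207 on the log2 scale, the inhibitory receptor gene CTLA4 by 1.49 ± 0.165 and the transcription factor gene BATF by 1.30. These genes had their highest level in T cells, whose share rose too, and within T cells 0 of 20 genes of the list rose and 2 fell (median log2 fold change -0.203, camera adjusted p 0.257, estimated-correlation p 0.699). Genes of immunoglobulin and plasma cell secretion fell (14 of 17, and 14 adjusted over the list alone, camera adjusted p 5.57e-14, estimated-correlation p 0.398), among them PRDM1 (-1.92), SDF2L1 (-1.85), EDEM1 (-1.35) and DERL3 (-2.25). Cell cycle genes fell (20 of 30, 22 adjusted over the list alone, 1.45e-08, estimated-correlation p 0.470), with PLK1 at -2.96, AURKA at -2.10 and KIF20A at -2.16, and each of these was highest in plasma cells. Erythroid genes fell in 9 of 12 (9 adjusted over the list alone, 4.65e-06, estimated-correlation p 0.451). Type I interferon genes fell on balance: 2 of 25 rose and 7 fell (2 and 11 adjusted over the list alone, 0.0151, estimated-correlation p 0.639), with IFI27L2 at -3.53, TRANK1 at -1.20 and IFIH1 at -1.10, all highest in erythroid cells, and IFI35 at 0.62. Of the inflammatory cytokines and chemokines 4 of 27 rose and 11 fell (7 and 13 adjusted over the list alone, 0.0482, estimated-correlation p 0.343), with LITAF, the TNF-inducing factor, at -2.56 ± 0.155, IL1B at -2.48, IFNG at -2.09 and IL18 at -1.52. LITAF and IL18 were highest in dendritic cells and IL1B in macrophages or monocytes, whose shares fell. Within macrophages or monocytes 0 of 17 genes of the list were called (camera adjusted p 0.308). Within NK or cytotoxic lymphocytes the list was called as higher at the preset correlation and did not pass with the estimated one. Of the iron and heme genes 1 of 16 rose and 4 fell (the same counts adjusted over the list alone, 0.0482, estimated-correlation p 0.398), with HMOX1 at -2.11, NCOA4 at -0.95 and SLC25A37 at -1.54; HMOX1 was highest in macrophages or monocytes and the other 2 in erythroid cells, whose shares fell.

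With the correlation estimated from the data none of these 7 lists passed. For the inflammatory list that correlation was -0.0242, below the preset 0.01, so a larger correlation among its genes was not the reason. By the fry test the type I interferon list was not called (adjusted p 0.0526), while the others of the 7 were. The inflammatory list was not called without Cobb control 1 or without infected Cobb replicate 1, and the iron and heme list was not called without any 1 of the infected Cobb replicates. The mitochondrially encoded genes, a measure of RNA quality, fell in 2 of 13 (0 adjusted over the list alone) and were not called as a list across all cells (camera adjusted p 0.272). This test used cells already cut at a mitochondrial share of 15%, so it cannot show that cell quality was alike. Among kept cells the median mitochondrial share was 7.87%, 7.78% and 7.75% in infected Cobb libraries and 10.4%, 10.9% and 9.87% in Cobb controls.

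Within T cells of infected Cobb birds, genes of the cell cycle list fell and genes of the MHC class I list rose. Cell cycle genes fell in 20 of 29 (22 adjusted over the list alone, camera adjusted p 1.14e-16, adjusted p 0.398 with the estimated correlation), with the replication genes MCM3 at -2.42, MCM5 at -2.08, RRM2 at -2.34 and MCM2 at -1.77. The mitochondrially encoded genes, a measure of RNA quality, were lower within T cells as a list (1 of 13 called, camera adjusted p 0.0223, estimated-correlation p 0.398), as were erythroid genes (2 of 3, 0.0126, estimated-correlation p 0.398). MHC class I genes rose in 4 of 10 (5 adjusted over the list alone, 0.0223, estimated-correlation p 0.398): B2M by 1.01, BF1 by 0.99, BF2 by 0.83 and TAPBP by 0.77 on the log2 scale. MHC class II genes fell in 4 of 8 and rose in 1 (the same adjusted over the list alone, 0.0326, estimated-correlation p 0.488), with BLB2 at -2.57, BLB1 at -2.06, CD74 at -1.07 and IFI30 at 0.55. BLB2 was at 13.7 ± 1.503 CPM in infected and 85.8 ± 50.9 in control T cells (n = 3 each) and at 11920 CPM in dendritic cells, whose share fell too, and RNA of the plasma cell genes IGLL1 and JCHAIN within T cells was at 44.6 ± 15.5 and 460.3 ± 212 CPM. FSTL4 rose to 46.8 ± 10.1 from 8.66 ± 7.29 CPM (n = 3 each; log2 fold change 2.59 ± 0.429, edgeR adjusted p 0.000999), SELENOW by 3.40 ± 0.733, CYB561D2 by 2.67 ± 0.551 and the ribosome assembly gene IMP3 by 3.84 ± 1.08. IMP3 was at 10.8 ± 6.04 CPM in infected birds and 0, 2.23 and 0 CPM in the controls, so its fold change rests on levels near 0. ADSS1 (-3.56 ± 0.801) fell to 0.886 ± 0.289 from 11.4 ± 3.71 CPM and SGMS2 (-3.16 ± 0.742) to 1.41 ± 1.00 from 11.4 ± 6.385 CPM. Both infected levels were near 0 as well. The mitotic gene CDC20 was at 4.84 ± 3.36 CPM in infected birds and 17.2, 15.6 and 122.6 CPM in the controls (-3.15 ± 0.787); without Cobb control 3 the change was -1.68 and the call was lost. JCHAIN, which joins antibody subunits, fell to 7.91 ± 4.35 from 88.5 ± 35.5 CPM (-3.49 ± 0.418), a level far below its 21250 CPM in plasma cells and within reach of free plasma cell RNA. Of 7980 genes, 1001 were called, 511 higher and 490 lower (DESeq2 1074; 2637 without overlap, 33.1% where chance gives 10%).

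The T cells of the groups also fell into different clusters. In infected Cobb birds 56.2% of T cells were in the largest cluster, whose leading genes included MTSS2, FHL3, CD28 and TCF7, and 1.34% in the next largest. In Cobb controls these were 20.4% and 32.4%, while a cluster led by division genes held 4.34% of T cells in infected and 5.78% in control Cobb birds, so the mix of T cell clusters differed between the groups as well. The T cell count was 606 to 666 without Cobb control 1, Cobb control 2, infected Cobb replicate 1 or infected Cobb replicate 2 (653, 666, 619 and 606), 641 with W-linked RNA as a covariate, 568 with classes from each library on its own and 2460 with a mitochondrial share of up to 30%.

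Within NK or cytotoxic lymphocytes of infected Cobb birds, genes of the inflammatory, cytotoxic, MHC class I and stress lists rose. CCL4 (ENSGALG00000032717), a chemokine, rose to 561.7 ± 129 from 54.4 ± 37.6 CPM (n = 3 each; log2 fold change 3.34 ± 0.536, edgeR adjusted p 0.00816), and CCL5 (ENSGALG00000043603) to 37.0 ± 9.13 from 4.33 ± 4.75 CPM (3.15 ± 0.498, adjusted p 0.000415). With MIF (1.92) and CCL1 (1.20) they were among 5 of 11 inflammatory genes that rose (6 up and 1 down adjusted over the list alone, camera adjusted p 0.000858, adjusted p 0.0553 with the estimated correlation). Of 14 cytotoxic genes 5 rose and 1 fell (7 and 1 adjusted over the list alone, 0.000534, estimated-correlation p 0.0553), with CD8BP at 0.86, EOMES at 0.84 and IL2RB at -0.60. MHC class I genes rose in 6 of 10 (6 adjusted over the list alone, 0.00206, estimated-correlation p 0.0968), with BF1 at 0.93, B2M at 0.86, BF2 at 0.82 and TAPBP at 0.79. Genes of the stress and dissociation response rose in 6 of 25 and fell in 1 (8 and 1 adjusted over the list alone, 0.00347, estimated-correlation p 0.528), with JUND at 1.45, DUSP1 at 1.08 and JUN at 0.99. Type I interferon genes rose in 1 of 22 and fell in 3 (1 and 5 adjusted over the list alone, 0.00330, estimated-correlation p 0.371), with MX1 at -1.55, TRANK1 at -1.51 and IFI35 at 0.75. The cells of this class fell into different clusters: the one led by GZMA, GNLY, CCL1 and CCL5 held 20.5% of them in infected and 1.41% in control Cobb birds, and the largest held 31.3% and 62.8%. FSTL4 (3.85 ± 0.676) and SELENOW (3.59 ± 0.687) rose, and MTSS1 (-2.35 ± 0.559) fell, as did JCHAIN (-3.60 ± 0.334) and IGLL1 (-2.97 ± 0.370), which free plasma cell RNA could also carry. F5 (-2.48 ± 0.728) was at 2.16 ± 1.03 CPM in infected birds and 6.24, 5.65 and 27.0 CPM in the controls, so that Cobb control 3 held most of the control level. Of 7755 genes, 847 were called, 530 higher and 317 lower (DESeq2 646). The count was 493 without Cobb control 2, 529 without infected Cobb replicate 3, 372 with W-linked RNA as a covariate, and 1309 and 1604 with the near-tie cluster left unnamed and with a mitochondrial share of up to 30%.

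In B cells 10 of 8475 genes were called between infected and control Cobb birds, 4 higher and 6 lower (DESeq2 47, 1059 at an unadjusted p under 0.05). DMA, an MHC class II loading gene, rose to 139.0 ± 65.9 from 25.7 ± 10.0 CPM (n = 3 each; log2 fold change 2.40 ± 0.393, edgeR adjusted p 0.0268) and SELENOW rose by 4.47 ± 0.665. The chaperone genes HSPH1 (-1.93 ± 0.321) and HSP90AA1 (-1.55 ± 0.280), NEUROD6 (-3.58 ± 0.469) and JCHAIN (-3.48 ± 0.392), which free plasma cell RNA could also carry, fell. The B cell cluster led by CPE and SH3BP2 held 17.6% of B cells in infected and 34.1% in control Cobb birds, and that led by MDK and CD72 held 21.9% and 8.24% (42, 37 and 316 cells in the infected libraries). MHC class II genes rose as a list with 1 of 9 called (3 adjusted over the list alone, camera adjusted p 4.80e-05, estimated-correlation p 0.224), and stress genes fell with 2 of 25 called (3 up and 6 down adjusted over the list alone, 0.00570, estimated-correlation p 0.400). In macrophages or monocytes 2 of 2723 genes were called (DESeq2 3, 211 unadjusted), and CDKN1A, an inhibitor of cell division, fell to 17.0 ± 20.5 from 306.7 ± 103 CPM (-4.27 ± 0.709, edgeR adjusted p 0.0211). CDKN1A was at 39.8, 0 and 11.2 CPM in the infected libraries, in sums of 53, 68 and 64 cells. The size of its fall thus rests on levels near 0. The macrophage cluster led by C1QC and C1QB held 36.2% of these cells in infected and 18.4% in control Cobb birds, and that led by CXCL13 and MARCO 29.7% and 39.8%. The B cell count ranged from 1 without Cobb control 1 to 30 without infected Cobb replicate 3 (3 without Cobb control 2 or infected Cobb replicate 2, 2 without Cobb control 3). The macrophage count ranged from 0 without infected Cobb replicate 2 to 21 without replicate 3 (1 without Cobb control 1 or infected Cobb replicate 1).

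The second comparison asked how the breeds differed without infection. NK or cytotoxic lymphocytes made up 30.3% ± 2.65 (SD, n = 3) of the cells of Cobb controls and 13.5% ± 0.663 (n = 3) of those of Beijing-you controls. B cells made up 10.3% ± 0.549 in Cobb and 28.6% ± 9.26 in Beijing-you, and T cells 18.9% ± 6.48 and 29.7% ± 3.26. The libraries of the breeds did not overlap in these 3 classes (exact permutation p 0.1 each, adjusted p 0.333). The NK or cytotoxic clusters carried CD3E at 736.6, 907.3 and 1014 CPM, against 880.5 to 1201 CPM in the T cell clusters. The T cell share thus depends on the class in which these cells were placed. CD3D over all cells overlapped between the breeds. It was at 460.4, 535.9 and 616 CPM in Cobb controls and 493.4, 543.1 and 569.9 CPM in Beijing-you controls. Plasma cells (14.2% ± 6.99 and 6.26% ± 3.15, exact permutation p 0.2), unnamed cells (p 0.3), granulocytes (p 0.3), macrophages or monocytes (p 0.5), erythroid cells (5.88% and 7.03% ± 1.20, p 0.8), dendritic cells (p 1) and thrombocytes (p 1) overlapped. Without a cell filter the difference was 6.50 points instead of 16.8 in NK or cytotoxic lymphocytes and -5.30 instead of -10.8 in T cells (exact permutation p 0.2), which was -6.23 at a mitochondrial share of up to 30% (p 0.3) and -7.07 without Cobb control 3. With each library clustered on its own the libraries overlapped in all 3 classes (p 0.3 for T cells, 0.4 for B cells, at -8.86 instead of -18.3 points, and 0.2 for NK or cytotoxic lymphocytes), and in B cells also under the stricter cell filter (-9.82, p 0.2).

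Between control birds BF1, GLDC and MMP13 were among the genes higher in Cobb, and P2RX7, PAX5 and PROM1 among those lower. BF1 (ENSGALG00000033932), a classical MHC class I gene, was at 693.2 ± 188 CPM (SD, n = 3) in Cobb and 141.9 ± 17.4 in Beijing-you (log2 fold change 2.29 ± 0.202 SE, edgeR adjusted p 0.00119). BF1 belongs to a family of close copies that vary between breeds, so reads can be shared between copies or lost against the reference allele. GLDC (ENSGALG00000015053), an enzyme of glycine breakdown, was at 15.7 ± 6.03 and 1.61 ± 0.864 CPM (3.19 ± 0.398, adjusted p 0.0114), with its highest level in NK or cytotoxic lymphocytes. MMP13 was at 30.3 ± 7.85 and 6.13 ± 1.59 CPM (2.30 ± 0.270, adjusted p 0.00882), and the glutathione transferase gene MGST1 at 27.8 ± 1.83 and 5.64 ± 3.39 CPM (2.35 ± 0.321). The other genes higher in Cobb were SLC66A3 (2.43 ± 0.473), ORMDL1 (2.15 ± 0.318), CCDC80 (1.90 ± 0.340), SLC16A9 (1.86 ± 0.357), HSF2BP (1.83 ± 0.390) and SH3PXD2B (1.75 ± 0.375).

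P2RX7 (ENSGALG00000003863), an ATP-gated channel, was lower in Cobb, at 24.6 ± 8.50 against 68.6 ± 10.1 CPM (n = 3 each; log2 fold change -1.497 ± 0.223, edgeR adjusted p 0.0144). PAX5 (ENSGALG00000016431), the transcription factor of the B lineage, was at 9.72 ± 3.26 and 26.9 ± 8.97 CPM (-1.43 ± 0.312, adjusted p 0.0482), and PROM1 at 32.1 ± 10.4 and 75.1 ± 9.54 CPM (-1.24 ± 0.222). The integrin gene ITGB7 (-1.58 ± 0.229), LGALSL (-1.91 ± 0.299), HLF (-1.51 ± 0.260), FRY (-1.35 ± 0.234) and the DNA repair gene SHLD2 (-1.35 ± 0.214), like PAX5 and PROM1, had their highest level in B cells, whose share was lower in Cobb. DOK5 (-1.94 ± 0.314) and RALGPS2 (-1.39 ± 0.297) were lower too. Of 11855 genes, 180 were called, 99 higher and 81 lower in Cobb, 44 without a symbol. DESeq2 called 658, 2416 genes had an unadjusted p under 0.05, and 2999 (25.3%, where chance gives 10%) did not overlap. Of the 20 named genes, BF1 alone kept its call under every alternative run. The count was 21 without Beijing-you control 2, 83 without Beijing-you control 3, 28 without Cobb control 1, 54 without Cobb control 3 and 328 without Cobb control 2, and the stricter cell filter left 8.

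Cytotoxic effector genes were higher in control Cobb birds in 2 of 15 (8 adjusted over the list alone, camera adjusted p 5.95e-06), and this list alone also passed with the estimated correlation (adjusted p 0.0375). IFNG was 1.499 higher and its transcription factor TBX21 1.24 higher on the log2 scale, while XCL1 (1.11, edgeR adjusted p 0.0702) and the granulysin gene GNLY (1.43, 0.0760) did not pass. The share of NK or cytotoxic lymphocytes was higher in Cobb as well (30.3% against 13.5%), and within these cells the list had 0 of 14 genes called (camera adjusted p 0.644, estimated-correlation p 0.802). The other lists higher in Cobb were MHC class I (1 of 10, 4 adjusted over the list alone, 5.95e-06, estimated-correlation p 0.0869), with TAPBP at 0.58 and BF2 at 0.75 not passing, and inflammatory cytokines (2 of 27, 4 adjusted over the list alone, 0.0173, estimated-correlation p 0.118), with LITAF at 0.73. With no member called over all genes, immunoglobulin secretion (5 of 17 adjusted over the list alone, 5.72e-06, estimated-correlation p 0.638), glycolysis and hypoxia (3 of 19, 0.00394, estimated-correlation p 0.0869), stress (2 of 25, 0.00507, estimated-correlation p 0.686) and cell cycle (0 of 30, 0.000310, estimated-correlation p 0.699) were higher in Cobb. Erythroid genes were lower (0 of 12 called, 0.0123, estimated-correlation p 0.686).

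Within classes, BF1 was higher in Cobb controls in T cells (468.3 ± 229 against 88.6 ± 24.6 CPM, n = 3 each; log2 fold change 2.39 ± 0.332, edgeR adjusted p 0.0319) and in NK or cytotoxic lymphocytes (2.02 ± 0.221, adjusted p 2.69e-05). P2RX7 was lower in T cells (33.1 ± 2.94 against 125.0 ± 48.5 CPM, -1.90 ± 0.307) and in B cells (-1.83 ± 0.288). The chemokine gene CCL1 was higher in NK or cytotoxic lymphocytes (232.9 ± 32.1 against 43.7 ± 17.6 CPM, 2.37 ± 0.272) and in B cells (3.998 ± 0.638). Over all libraries CCL1 was at 10.3 CPM in B cells and 1806 CPM in dendritic cells, so free RNA of other classes could also carry its B cell difference. In T cells 7 of 7980 genes were called, 2 higher and 5 lower (DESeq2 72, 935 unadjusted). SRGAP3 was also higher (1.56 ± 0.287), and SAP30L (-2.04 ± 0.373), ZNF830 (-1.29 ± 0.213) and MTMR3 (-0.93 ± 0.172) were lower. In NK or cytotoxic lymphocytes 16 of 7755 were called, 10 higher and 6 lower (DESeq2 82, 898 unadjusted). GLDC (3.03 ± 0.569) and CLTA (2.87 ± 0.523) were higher, and HDC, which makes histamine (-3.95 ± 0.537), DOK5 (-2.34 ± 0.423), PLAGL1 (-2.28 ± 0.404) and LRRCC1 (-1.93 ± 0.368) were lower. In B cells 15 of 8475 were called, 8 higher and 7 lower (DESeq2 96, 1301 unadjusted). SLC16A9 (2.62 ± 0.402), the heme oxygenase gene HMOX1 (2.05 ± 0.386) and HSPH1 (1.95 ± 0.332) were higher, and RADX (-2.13 ± 0.394), AHR (-1.59 ± 0.229) and SHLD2 (-1.59 ± 0.286) were lower. HMOX1 was at 30.1 CPM in B cells and 1040 CPM in macrophages or monocytes over all libraries, so free RNA could carry this difference too. The mix of clusters differed too: the largest B cell cluster held 49.2% of B cells in Cobb and 86.3% in Beijing-you controls and the next 34.1% and 5.40%, and the second largest T cell cluster held 32.4% and 59.1% of T cells. In macrophages or monocytes edgeR and DESeq2 each called 0 of 2723 genes (95 at an unadjusted p under 0.05).

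MHC class I genes were higher in Cobb as a list in T cells (1 of 10 called, camera adjusted p 0.000162, estimated-correlation p 0.0755) and in NK or cytotoxic lymphocytes (2 of 10, 4 adjusted over the list alone, 3.07e-05, estimated-correlation p 0.0833). The within-class breed counts changed with single libraries. The T cell count was 0 without Beijing-you control 1 or Cobb control 1, 4, 2, 3 and 1 without Beijing-you control 2, Beijing-you control 3, Cobb control 2 and Cobb control 3. The NK count was 9 without Beijing-you control 1 or 3 and 44 without Cobb control 2. The B cell count was 0 without Beijing-you control 2, Beijing-you control 3 or Cobb control 2, 2 without Cobb control 1 and 1 without Cobb control 3, and the macrophage count was 1 without Beijing-you control 3.

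The third comparison asked how infection changed Beijing-you birds, with 1 infected bird and 3 controls. In the infected library T cells made up 53.3% of cells (95% interval 51.7 to 54.9), against 29.7% ± 3.26 in controls, and B cells 18.7% (17.4 to 19.9) against 28.6% ± 9.26. Plasma cells made up 5.93% (5.21 to 6.72) against 6.26% ± 3.15, erythroid cells 4.29% (3.67 to 4.97) against 7.03% ± 1.20, and NK or cytotoxic lymphocytes 5.31% (4.63 to 6.06) against 13.5% ± 0.663. Macrophages or monocytes made up 3.29% (2.75 to 3.89), dendritic cells 3.21% (2.68 to 3.81), granulocytes 0.359% (0.197 to 0.602) and thrombocytes 0.282% (0.141 to 0.505). CD3D (ENSGALG00000007418), a chain of the T cell receptor complex, was at 1661 CPM against 535.5 ± 38.8 (log2 fold change 1.63 ± 0.182, edgeR adjusted p 0.0143). ABCA2 (56.0 against 20.1 ± 2.44 CPM, 1.47 ± 0.221, adjusted p 0.0446) and the purine synthesis gene ADSL (268.0 against 126.6 ± 16.6 CPM, 1.08 ± 0.162, 0.0446) were also higher. Of 11855 genes 7 were called, all higher and 4 without a symbol (DESeq2 258, 1770 unadjusted). Stress genes were lower as a list with 0 of 25 called (camera adjusted p 0.0317, estimated-correlation p 0.9501), with DNAJA1 at -1.22 and HSP90AA1 at -1.49. The call of CD3D was lost without Beijing-you control 1 and under the stricter cell filter, and those of ABCA2 and ADSL under 7 and 6 of 13 alternatives. The gene count was 0 without Beijing-you control 1, 4 without control 2, 12 without control 3, and 713 without a cell filter.

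The fourth comparison set infected Cobb birds against the infected Beijing-you bird. HINTW was at 0.993, 0 and 0.229 CPM in the infected Cobb libraries and at 1245 CPM in the infected Beijing-you library. Breed and W-linked RNA were thus fully aligned among these birds. CEBPD was at 144.6 ± 42.5 CPM in Cobb (SD, n = 3) and 22.9 in the Beijing-you bird (log2 fold change 2.66 ± 0.395, edgeR adjusted p 0.0104), and BF1 at 785.3 ± 91.1 and 134.4 (2.55 ± 0.320, adjusted p 0.00546). FSTL4 (4.89 ± 0.882), GLDC (3.52 ± 0.562) and the TNF receptor family gene TNFRSF25 (52.8 ± 13.5 against 10.3 CPM, 2.36 ± 0.440) were also higher in Cobb. YF5, another MHC class I family member with close copies, was at 7.07 ± 4.28 and 322.1 CPM (-5.47 ± 0.562, adjusted p 0.00546). HBAD (-9.73 ± 1.65), HBBA (-9.18 ± 1.29), HBA1 (-9.10 ± 1.55) and TAL1 (-5.10 ± 0.542) were lower in Cobb. Of 11855 genes 307 were called, 119 higher and 188 lower in Cobb, 74 without a symbol (2326 unadjusted). DESeq2 called 719, of which 52.7% were higher in Cobb, against 38.8% with edgeR. The calls of the haemoglobin genes were lost under 6 of 12 alternatives, and those of FSTL4 and TNFRSF25 under 5 and 4 of 13. The count was 104 without infected Cobb replicate 1 and 50 without replicate 2.

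In the same comparison T cell activation genes were higher in Cobb as a list (0 of 20 called, 12 up and 1 down adjusted over the list alone, camera adjusted p 3.91e-06, estimated-correlation p 0.123). Immunoglobulin secretion genes were lower (4 of 17 called, 12 adjusted over the list alone, 4.68e-10, estimated-correlation p 0.363), with TXNDC5 at -3.81 and JCHAIN at -3.62, as were erythroid genes (5 of 12, 9 adjusted over the list alone, 3.53e-13, estimated-correlation p 0.183). Cytotoxic effectors (0.00242) and stress genes (8.52e-05) were higher in Cobb. Type I interferon (0.000419), MHC class II (0.0102), iron and heme (0.0163), cell cycle (0.00788) and thrombocyte genes (0.000884) were lower, and none of these passed with the estimated correlation.

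The fifth comparison tested whether infection acted differently in the breeds. Collagenase MMP13 fell in Cobb (-5.33) and was little changed in Beijing-you (0.45), a difference of -5.78 ± 0.470 on the log2 scale (edgeR adjusted p 0.000232). TXNDC5, an isomerase of antibody-secreting cells, was at 81.2 ± 15.8 CPM in infected and 1519 ± 786 in control Cobb birds (n = 3 each), and at 1142 in the infected Beijing-you bird and 759.9 ± 422 in its controls (n = 3). The effect on FSTL4 was 4.85 in Cobb and -0.44 in Beijing-you (difference 5.29 ± 1.13). Of 11855 genes 219 were called, 36 with a more positive and 183 with a more negative effect in Cobb (DESeq2 658, 2334 unadjusted), and of the named genes only MMP13 kept its call under every alternative run. The count was 343, 26 and 110 without Beijing-you control 1, 2 or 3, 60, 381 and 93 without Cobb control 1, 2 or 3, and 27, 22 and 494 without infected Cobb replicate 1, 2 or 3.

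Of the 3319 genes called in Cobb, 2237 (67.4%, 95% interval 65.8 to 69.0) changed in the same direction in Beijing-you, with a Pearson r of 0.298 across genes, which are not independent replicates. The share was 75.1% among genes higher and 60.5% among genes lower in infected Cobb birds. In both breeds infected birds had a larger T cell share and a lower median mitochondrial share. Whether these gave the shared direction was not tested. With the stricter cell filter the shared direction was 49.8% (47.3 to 52.3) and r 0.0664, and without Beijing-you control 1 r was 0.182.

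**Figure D3:**
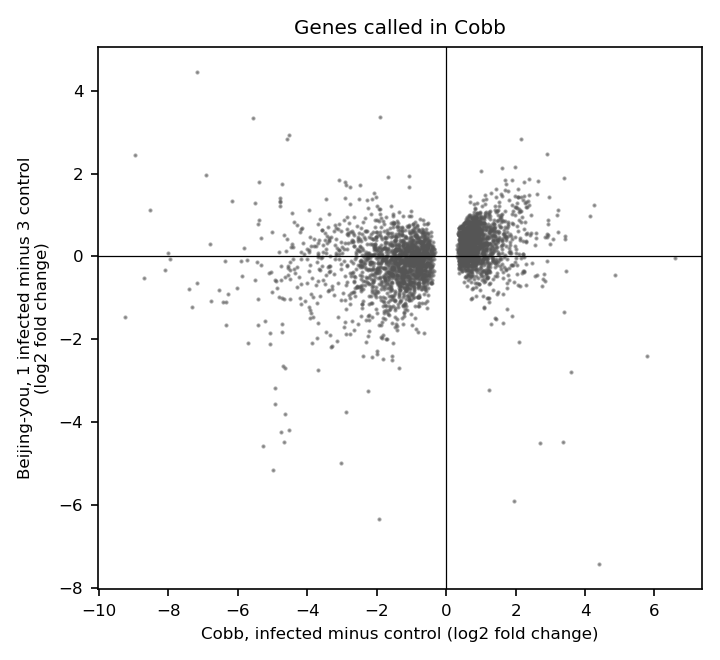
Log2 fold change with infection in Beijing-you (y axis, 1 infected bird) against that in Cobb (x axis, 3 infected birds) for the 3319 genes called in Cobb; each point is a gene. The changes had the same sign for 67.4% of the genes.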

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

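The test of the difference between the breeds' infection effects was set before the data were examined; every test of an explanation in the paragraphs that follow it was chosen after the result it concerns had been seen.

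The difference between the infection effects of the 2 breeds was itself tested. In all CD45+ cells, 219 genes had a different infection effect in the 2 breeds (edgeR test of the difference, 3 infected Cobb birds and 1 infected Beijing-you bird). The difference, Cobb minus Beijing-you on the log2 scale, was -5.78 for MMP13 (-5.33 in Cobb and 0.45 in Beijing-you), -5.27 for RLN3 (-1.89 and 3.38), -5.18 for CNTNAP1 (-4.67 and 0.52), -4.84 for AK1 (-4.14 and 0.69) and -4.81 for TXNDC5 (-4.22 and 0.59), all highest in plasma cells. It was 5.29 for FSTL4 (4.85 and -0.44), 2.76 for TNFRSF25 (2.07 and -0.69), 2.36 for ABI3 (1.497 and -0.86), 2.31 for PARP8 (1.09 and -1.22) and 2.15 for ITGB7 (1.34 and -0.81). With a single infected Beijing-you bird, these differences cannot be separated from features of that bird, and the labels say that the sort of the other 2 chosen birds of its group gave too few cells.

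Among gene lists, the adjusted camera p of the difference, with the adjusted p at the estimated correlation in brackets, was 9.33e-16 for immunoglobulin and plasma cell secretion (0.245; 6 of 17 genes lower), 2.44e-07 for erythroid genes (0.245), 1.12e-05 for cell cycle (0.553), 0.0122 for type I interferon (0.553), 0.0138 for inflammatory cytokines and chemokines (0.187), 0.0239 for iron and heme handling (0.245) and 0.0465 for the interferon gamma response (0.264), all more negative in Cobb. For the inflammatory list the median difference was -0.683 and the mean 0.082, of opposite sign. T cell activation genes were more positive in Cobb (0.000215, adjusted p 0.187 with the estimated correlation). With the estimated correlation 0 of these 8 lists passed.

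Plasma cells, erythroid cells and their RNA were scarce in the infected Cobb libraries. The mitochondrial filter was not the whole cause: without any cell filter plasma cells made up 0.330% ± 0.0787 of infected and 3.24% ± 0.843 of control barcodes (n = 3 each), a ratio of 0.102. A loss of these barcodes in cell calling, from a suspension that held them, would leave their free RNA in other droplets, yet IGLL1 and JCHAIN within T cells were at 44.6 ± 15.5 CPM in infected and 460.3 ± 212 in control Cobb birds (ratio 0.0969), and haemoglobin in all cells not erythroid was at 0.574 ± 0.551 (15 UMIs) and 16.0 ± 3.01 CPM (222 UMIs, ratio 0.0358), while GNLY within B cells was at 55.8 ± 4.63 and 31.7 ± 4.74 CPM. Sorting or handling that differed between birds stays open, since plasma cells made up 5.93% of the infected Beijing-you library and the labels do not give the handling of each bird; for erythroid cells, which a sort on CD45 is meant to leave out, this includes the purity of the sort. A loss of plasma cells from the spleen with infection is thus a candidate explanation for Cobb that cannot be told apart from handling.

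T cells took a larger share of the infected Cobb libraries. Without a cell filter the difference was still 17.2 points (50.8% ± 2.40 against 33.6% ± 1.66, n = 3 each). All barcodes were also clustered and named anew without the filter, so cells could change class. NK or cytotoxic lymphocytes of Cobb controls were at 15.19% there, against 30.3% among kept cells. The step from 17.2 to 37.2 points may thus come from the cell filters, from the new naming or from both. A difference remained without the cell filters, the mitochondrial one among them, so they were not its whole cause. Among kept cells neither plasma nor erythroid the difference in T cell share was 33.2 points (56.5% ± 4.35 against 23.3% ± 6.20), which the loss of plasma and erythroid cells alone would not give. Infection and a difference in cell quality or handling between infected and control birds stay open.

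Many genes differed between infected and control Cobb birds. With W-linked RNA as a covariate 2428 genes were called, and 66.0% of the original calls were among them, so an unequal number of birds with W-linked RNA was not the whole cause. It may account for part of the other calls, although a covariate also leaves the test less power. A changed share of the classes does not by itself enter sums within a class, and 1001 genes were called within T cells. These sums also held free RNA of other classes. IGLL1 and JCHAIN within T cells were at 44.6 ± 15.5 CPM in infected and 460.3 ± 212 in control Cobb birds. The 1001 calls thus cannot decide how much a changed mix of classes gave. Free RNA, a changed mix of T cell clusters, W-linked RNA and the cell quality that differed with infection stay open for those 1001 genes, beside infection itself.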

How the results depend on the processing

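Tests were repeated with the alternatives set in advance. The mitochondrial share of up to 30%, W-linked RNA as a covariate, the near-tie cluster left unnamed and, for the direction of the response, all settings except DESeq2 and the replicates left out were chosen after seeing the data. Of the named genes, over all settings, 1334 results kept direction and call and 401 kept direction but lost the call, and of the lists called 556 kept both, 180 lost the call and 1 reversed. For every change below the cause was not tested, except that fewer cells or libraries were used in the equal draw, the stricter filter, the 6-library fit and the replicates left out. The count for infection in Cobb in all cells (3319) stayed within 1.5 times its value in every setting run except the stricter cell filter (1623) and without infected Cobb replicate 1 or 2.

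With RLE size factors the count for infection in Beijing-you was 2 instead of 7, and that for breed in T cells 3 instead of 7. With DESeq2 the counts were 658 instead of 180 for control breeds, 258 for infection in Beijing-you, 719 instead of 307 for infected breeds and 658 instead of 219 for the difference in effect. For breed DESeq2 called 72 genes in T cells, 82 in NK or cytotoxic lymphocytes instead of 16 and 96 in B cells instead of 15, and for infection in Cobb 47 in B cells instead of 10. DESeq2 changed the percent higher among called genes from 100 to 61.6 for infection in Beijing-you, from 38.8 to 52.7 for infected breeds and from 16.4 to 34.4 for the difference in effect, and leaving out abundant genes changed it from 55 to 45 for control breeds. With no low-count filter the counts were 437 for control breeds, 195 for infection in Beijing-you, 479 for infected breeds and 396 for the difference. Within classes it gave for breed 133 in T cells, 167 in NK or cytotoxic lymphocytes, 270 in B cells and 3 in macrophages or monocytes, and for infection in Cobb 201 in B cells and 4 in macrophages or monocytes.

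Without a cell filter infection in Beijing-you called 713 genes. In points of share, infected minus control Cobb, T cells were then at 17.2 instead of 37.2, plasma cells at -2.91 instead of -13.6, dendritic cells at -4.18 instead of -3.34, erythroid cells at -1.57 instead of -5.86, and NK or cytotoxic lymphocytes reversed to 3.07 from -11.9. The breed difference in NK or cytotoxic lymphocytes was 6.50 instead of 16.8 points. The direction shared with Beijing-you was 74.1% instead of 67.4%. The stricter cell filter kept 2436 cells and gave 8 genes for control breeds, 2 for infection in Beijing-you, 525 for infected breeds and 392 for the difference. Under it the shares in Cobb changed by 64.5 points for T cells, 0.436 for B cells (5.05 before), -41.6 for plasma cells, -6.89 for macrophages or monocytes (-3.74 before), -2.09 for dendritic cells, -8.99 for NK or cytotoxic lymphocytes and -2.65 for erythroid cells. The breed differences were 24.0 points for plasma cells (7.95 before), 13.2 for NK or cytotoxic lymphocytes, -5.47 for erythroid cells (-1.15 before) and, reversed, -4.74 for dendritic cells (0.151 before). The shared direction was 49.8% (95% interval 47.3 to 52.3, which treats genes as independent), with r 0.0664.

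With a mitochondrial share of up to 30% (46624 cells) the counts were 395 for control breeds, 593 for infection in Beijing-you, 2460 in T cells and 1604 in NK or cytotoxic lymphocytes for infection in Cobb, and 38, 96 and 26 for breed in T cells, NK or cytotoxic lymphocytes and B cells. Lists called were 6 instead of 1 for infection in Beijing-you, 4 instead of 1 for breed in NK or cytotoxic lymphocytes and 9 instead of 4 for infection in Cobb macrophages or monocytes, and the glycolysis and hypoxia list in Cobb T cells reversed (adjusted p 0.829). Share changes in Cobb were 20.8 points for T cells, -4.16 for plasma cells, -1.91 for macrophages or monocytes, -1.38 for NK or cytotoxic lymphocytes and -1.89 for erythroid cells, the breed difference of NK or cytotoxic lymphocytes was 9.81, and the shared direction 70.8%. With W-linked RNA as a covariate the counts were 114 for infected breeds and 97 for the difference, and for infection in Cobb 641 in T cells, 372 in NK or cytotoxic lymphocytes, 5 in B cells and 1 in macrophages or monocytes. For breed they were 32 in T cells, 28 in NK or cytotoxic lymphocytes and 4 in macrophages or monocytes instead of 0. Lists called were 0 for infection in Beijing-you, 3 instead of 6 in Cobb T cells and 8 in Cobb macrophages or monocytes for infection, and 3 in NK or cytotoxic lymphocytes and 4 instead of 2 in macrophages or monocytes for breed. The shared direction was 65.1%.

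An equal draw of cells gave 65 genes for control breeds, 1 for infection in Beijing-you, 132 for infected breeds and 83 for the difference. With only the 6 libraries compared, control breeds had 75 genes in all cells, 4 in T cells and 43 in B cells, and infection in Cobb had 21 in B cells and 0 in macrophages or monocytes. With each library clustered on its own, infection in Cobb had 568 genes in T cells and 0 in macrophages or monocytes, and breed had 1 in T cells, 50 in NK or cytotoxic lymphocytes and 0 in B cells. The shares then changed in Cobb by -2.38 points for dendritic cells, -21.7 for NK or cytotoxic lymphocytes and -2.68 for erythroid cells, and between breeds by -8.86 for B cells (-18.3 before), 13 for NK or cytotoxic lymphocytes and, reversed, -0.728 for dendritic cells. Leiden resolution halved gave a breed difference of 10.5 points in NK or cytotoxic lymphocytes. The near-tie cluster left unnamed gave 10.6 points there, and 1309 genes for infection in Cobb and 103 for breed in that class.

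The labels number the replicates without saying that numbers pair, and residuals of birds with the same number had r from -0.088 to 0.243 across genes, against -0.243 to 0.204 for birds with different numbers. With the replicate block, which leaves out the infected Beijing-you bird, breed had 12 genes in T cells and 79 in NK or cytotoxic lymphocytes, and infection in Cobb had 31 in B cells and 1 in macrophages or monocytes. Lists called with the block were 4 for breed in NK or cytotoxic lymphocytes and 1 in macrophages or monocytes. The other counts with the block stayed within 1.5 times their value.

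With the estimated correlation 0 lists were called in every comparison and population except control breeds in all cells, with 1 of 8, the cytotoxic effectors. The fry test called more. In all cells it called 8 of 21 lists for infection in Cobb and 4 for control breeds. Within T cells, NK or cytotoxic lymphocytes, B cells and macrophages or monocytes it called 6, 6, 1 and 0 for infection in Cobb. For breed these were 2, 1, 1 and 0.

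Leaving out each replicate of the groups compared in turn gave 2141 to 3211 genes for infection in Cobb (3314, 3318 and 3317 without Beijing-you control 1, 2 or 3), 21 to 328 for control breeds, 0 to 12 for infection in Beijing-you, 50 to 309 for infected breeds and 22 to 494 for the difference. Within classes the range for infection in Cobb was 606 to 786 in T cells, 493 to 742 in NK or cytotoxic lymphocytes, 1 to 30 in B cells and 0 to 21 in macrophages or monocytes. For breed it was 0 to 4, 9 to 44, 0 to 11 and 0 to 1 in the same order. Lists called ranged from 0 (without Beijing-you control 1) to 4 (without control 3) for infection in Beijing-you, and from 0 (without infected Cobb replicate 2; 2 without Cobb control 1) to 5 for infection in Cobb macrophages or monocytes. For breed they ranged from 3 (without Beijing-you control 3; 4 without Cobb control 1) to 9 in T cells, from 1 to 5 in NK or cytotoxic lymphocytes (5 and 3 without Beijing-you controls 2 and 3, and 2, 3 and 4 without Cobb controls 1, 2 and 3), from 3 (without Cobb control 3) to 6 in B cells and from 1 (without Beijing-you control 2) to 4 (without control 3) in macrophages or monocytes. The shared direction ranged from 65.8% to 71.4%, and its r from 0.182 (without Beijing-you control 1) to 0.376.

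Left out in turn, the breed difference of macrophages or monocytes ranged from -0.303 (without Cobb control 1) to 1.96 points, and was -0.0256 without Beijing-you control 2. That of dendritic cells ranged from -1.07 (without Beijing-you control 1) to 1.96, and was -0.430 without Beijing-you control 2 and -0.0186 without Cobb control 3. That of erythroid cells ranged from -2.07 to 0.633 (without Cobb control 1). The share changes in Cobb of T, B, plasma, dendritic and erythroid cells, macrophages or monocytes and NK or cytotoxic lymphocytes kept their direction in every library left out, from 33.4 to 39.5 points for T cells and from -17.1 to -10.1 for plasma cells, as did the breed differences in T cells (from -12.9 to -7.07), B cells and NK or cytotoxic lymphocytes. Among the 4 classes tested, depth limits macrophages or monocytes most: a library held as few as 43 of these cells, and 2723 genes could be tested against 7980 in T cells.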

Other observations

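The tests of other groupings of the libraries, given at the end, were chosen after the counts had been seen. The named classes held distinct states. Among T cell clusters, 1149 cells led with TNFRSF4, CTLA4, ICOS and BATF, genes of activated and regulatory T cells, 1091 cells led with CD8A, IL7R and LEF1, and 468 cells led with division genes such as TOP2A and CENPF. Beijing-you T cells sat mostly in the second largest cluster, 59.1% in controls and 71.1% in the infected bird, with 10.1% and 7.61% in the largest. Of the NK or cytotoxic class, 535 cells led with GZMA, GNLY, CCL1 and CCL5. Unnamed cells included 1458 that expressed CD3E and led with LIFR, FSTL4, IKZF2 and KIT, 144 that led with EXFABP, S100A12, MMP9 and CSF3R, genes of granulocytes and monocytes, and 102 that led with HDC and GATA2, genes of basophils and mast cells. The 102 cells also carried the T cell genes CD3E (1176 CPM) and CD3D (6061 CPM, the highest of the clusters), so their identity stays open.

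Lists that camera did not call for infection in Cobb across all cells still held called genes. The fry test called the cytotoxic effectors as higher and the glycolysis list as lower (adjusted p 0.0120 each). NF-kB feedback genes rose in 3 of 26 and fell in 7 (camera adjusted p 0.479), with the inhibitor gene NFKBIA at 1.51, BIRC3 at 0.89 and the lipopolysaccharide receptor gene TLR4 at -2.18. Interferon gamma response genes rose in 3 of 16 and fell in 3 (0.482), with IRF1 at 0.87, IRF8 at -1.90 and IL15 at -2.002. Cytotoxic effectors rose in 5 of 15 and fell in 2 (0.272), with CD8BP at 1.04 and CD8A at 0.82. MHC class I genes rose in 1 of 10 and fell in 2 (0.504), with TAP1 at 0.71 and CALR at -2.16. MHC class II genes rose in 2 of 10 and fell in 1 (0.709), with DMA at 1.42 and BLB2 at -1.32. Stress genes rose in 5 of 25 and fell in 5 (0.709), with JUN at 0.94 and HSPD1 at -1.57. Complement and phagocytic receptors rose in 2 of 23 and fell in 3 (0.374), with LAPTM5 at 1.03 and CYBB at -1.78. Glycolysis genes rose in 1 of 19 and fell in 4 (0.487), and cholesterol genes rose in 4 of 25 and fell in 3 (0.383).

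Antimicrobial peptide genes were called in 0 of 10 (0.823), thrombocyte genes fell in 2 of 8 (0.136), granulocyte genes fell in 1 of 11 (0.383), and stromal genes rose in 1 of 9 and fell in 2 (0.562). The median and mean log2 change differed in sign for MHC class I (0.02 and -0.23, tested as lower) and for cholesterol genes (0.26 and -0.14, tested as higher). For antimicrobial genes the median was 0, the mean -0.21 and the tested direction higher.

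Further lists were called within classes at the preset correlation, and 0 within any class passed with the estimated one. For infection in Cobb, T cells also had lower glycolysis genes (1 of 17 rose and 3 fell, camera adjusted p 0.0326), a list that was not called and turned higher at a mitochondrial share of up to 30% (adjusted p 0.829). NK or cytotoxic lymphocytes also had higher cell cycle genes (1 of 26, STMN1 at 1.60, 0.0106) and higher complement and phagocytic receptors (3 of 11 rose, 0.0349). In B cells the lists of cell cycle (1.08e-06), erythroid genes (0.00246), NF-kB feedback (0.00570), inflammatory cytokines (0.0102) and iron and heme (0.0270) were lower, and cholesterol (0.0168) and MHC class I (0.0218) higher, each with 0 genes called by edgeR over all genes tested. In macrophages or monocytes type I interferon genes were lower as a list (0 of 9 called, 0.000491), and so were immunoglobulin genes (0.00726) and NF-kB feedback (0.0210), while MHC class II was higher (0.0210).

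Between control breeds, T cells of Cobb also had higher lists of cell cycle (2.63e-08), glycolysis (0.00106), cytotoxic effectors (0.00940), T cell activation (0.0304), stress (0.0304) and NF-kB feedback (0.0483), and lower erythroid genes (0.0161). B cells of Cobb had higher lists of stress (1 of 25 rose, 8.50e-07), cell cycle (8.12e-09), immunoglobulin secretion (0.00352), glycolysis (0.0131) and inflammatory cytokines (1 of 13 rose, 0.0194), and lower erythroid genes (0.0282). Macrophages or monocytes of Cobb had higher MHC class I (0.0174) and immunoglobulin secretion (0.0250).

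The 6 libraries of each main comparison can be split into groups of 3 in 10 ways, which is too few for a share under 0.05. Every split other than the real one mixes both groups on each side. A large difference between the groups, whatever its cause, then adds to the spread, so low counts in those splits lend no separate weight. For infection in Cobb the real split called 3319 genes in all cells and the highest other split 0. The real and highest other counts were 1001 and 1 in T cells, 847 and 2 in NK or cytotoxic lymphocytes, and 10 and 2 in B cells, where 1 of the 10 splits, the real one, was as large. In macrophages or monocytes they were 2 and 13, with 3 splits as large. Between control breeds the real and highest other counts were 180 and 9 in all cells, 7 and 0 in T cells, 16 and 2 in NK or cytotoxic lymphocytes, and 15 and 0 in B cells, and in macrophages or monocytes 0 and 8, with all 10 splits as large.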
